A study of Caenorhabditis elegans with 2 samples.

How the data were processed

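ChIP-seq with an antibody against GFP was done on whole late embryos of strain OP311, which expresses TBX-7 fused to GFP and FLAG, in 2 biological replicates, per the labels. The description of each sample names an anti-GFP antibody and its antibody field names tbx-7. The field was read as the target, and the antibody as anti-GFP. Both replicates form 1 group, and no comparison between groups was possible. The 8 peak lists used are narrowPeak tables in 2 genome versions, ce10 and ce11: a list after the IDR test, a series-wide list before that test, and 1 such list for each replicate. Per the metadata deposited with each sample, each replicate list was called on the alignment of that replicate against 1 control alignment, the series-wide list on both replicates against the control, and the IDR list was derived from these 3. The same control served both replicates. The aligner, the peak caller, their versions and the read depth were not given in the sources used here, and control reads were not used here.

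Column 7 of each list holds the signal of a peak as deposited by the authors, on the scale of their caller, and column 9 holds the −log10 of its q-value, as deposited by the authors. Both are set within a list, so signal was used only to rank, filter and describe peaks within its own list and for the correlation between replicates, which rests on ranks and log2 values. The lists taken before the IDR test were made permissive for that test, so most of their peaks are weak, and their lengths were not compared as a result. Where 2 neighbouring summits share an interval the interval is listed 2 times, as happened for 2 intervals of the IDR list, and each summit was kept.

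Summits (start plus the offset in column 10) of the ce11 lists were placed on the Ensembl release 115 annotation and the RefSeq sequence of WBcel235, which is ce11. No coordinates were converted, and the ce10 lists were used only for counts and replicate comparisons, with ce11 chromosome lengths. A promoter was 1000 bp upstream to 200 bp downstream of the start of a protein-coding gene. Other summits were classed in turn as 5′ untranslated, coding exon, 3′ untranslated, intron and intergenic, so that a small RNA gene outside protein-coding genes counts as intergenic. Random expectation came from 1000 seeded circular shifts of the summits along each chromosome, which keep their spacing but not their relation to mappable or open sequence. Interval overlap alternatives used 200 shifts, and the correlation over all matched peaks used 10000 pairings in place of 100000.

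A gene was bound when at least 1 IDR summit lay in its promoter. The 24 gene lists, 12 written gene by gene and 12 symbol families, were fixed before the data were examined and compared with all other protein-coding genes by Fisher's exact test with Benjamini-Hochberg adjustment over the lists. They were T-box factors, body wall muscle, pharynx, intestine, epidermis, pan-neuronal, ciliary, germ line, developmental transcription factors, Wnt pathway, Notch pathway, heat shock and stress, ribosomal proteins, histones, collagens, nuclear hormone receptors, ceh homeobox, hlh, C-type lectins, chemoreceptors, F-box proteins, respiratory chain, proteasome, and translation factors with tRNA synthetases. A symbol family holds only genes with the chosen symbols, so other genes of its class were counted among the other genes. Genes of a list can share a summit, which the test takes as independent. Words were counted on both strands in windows of 50 bp to either side of the summit and of points 500 bp away, and tested with the exact McNemar test, using alternate flanks. Chromosome counts were tested with exact binomial tests against length. Shares carry Wilson or exact 95% intervals, which cover counting error only, and a count of 0 was given the limit of 3 counts. The threshold was an adjusted p of 0.05.

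Genes were named by a rule fixed before the data were examined: tbx-7, bound T-box genes, the promoter-bound genes of the 20 strongest IDR peaks, and for each list at most 4 bound members with the strongest peaks. Of six-mers, the 5 with the smallest adjusted p in each direction were named. Alternatives fixed in advance were other promoter windows, nearest gene starts, the 345 strongest peaks, leaving out the strongest 10% of peaks, the ce10 lists, other distances for shared summits, other windows and flanks, shorter T-box words, upstream distance in a logistic model, and leaving out each replicate by using the 690 strongest peaks of the other. Alternatives added after the data were seen were shuffled windows, gene lists without peaks holding enriched words, gene starts sharing a summit counted once, and gene lists, location and six-mers without peaks beside small RNA genes.

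The scripts were tested on simulated data. For summit location with 690 uniform summits, 0 of 20 runs were called, and with summits placed in promoters 20 of 20 were. For gene lists over 19973 genes, uniform summits gave 1 call in 480 list tests, 10 summits planted at ribosomal protein genes were found in 20 of 20 runs, and 3 of 460 other lists were called in those runs. The simulated summits were not matched to the share of real summits that lie in several promoters. These rates therefore do not cover the dependence between genes that share a summit. For six-mers, 1 flank of each summit against the opposite flank, with sides alternating by rank, gave 0 calls among 2080. A word planted in 10% of 690 windows was recovered with 3 of its 3 six-mers. Both sides of this test were flanks, so it does not cover calls that come from the higher GC content of summit windows. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.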

Results

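Genomic occupancy of TBX-7, a T-box family transcription factor of the nematode Caenorhabditis elegans, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole late embryos. The hermaphrodite strain OP311 carries a transgene that expresses TBX-7 fused at its C terminus to GFP and FLAG, and chromatin was recovered with an antibody against GFP, per the sample descriptions, while the antibody field of both samples names tbx-7, the tagged protein. Embryos were collected 3 h after synchronization by bleaching of eggs. The design held 1 group with 2 biological replicates, so peaks were compared between replicates, with shifted positions, with flanking sequence and between sets of genes, but not between conditions. Peak lists carry no read totals, and the sequencing depth of each library was not given in the sources used here. All coordinates are 1-based positions on ce11 (WBcel235).

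The final list of the authors, which had passed a test of irreproducible discovery rate (IDR) between replicates, held 690 peaks. The strongest lay in the promoters of K12H4.5, M01F1.9, lin-35 with vps-51, and cux-7 with lig-4 and C07H6.2, and these 4 peaks led the list of each replicate in the same order. These 690 were the 690 strongest of the 8759 peaks listed before the IDR test on both replicates together. Replicate 1 had 16060 and replicate 2 had 9840 peaks before that test, of which 1066 and 621 had a −log10 q of at least 2. Signal values, which are the authors' own and are on the scale of their peak caller, ran from 86 to 1661 in the final list with a median of 134. The ce10 version of the list held 687 peaks.

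Of the 690 peaks, 664 had a summit within 100 bp in both replicate lists, 683 in replicate 1 and 671 in replicate 2. When the 690 strongest peaks of each replicate were set against each other, 494 matched within 100 bp, a share of 71.6% (Wilson 95% interval 68.1 to 74.8%). After circular shifts of replicate 2 along each chromosome the mean share was 0.142% and the highest of 1000 shifts was 0.725% (one-sided permutation p = 0.001, the smallest 1000 shifts can give). Across the 664 peaks found in both replicates, signal was correlated between replicates with Spearman's rho = 0.75 and, on the log2 scale, Pearson's r = 0.81 (permutation p = 1e-05 for each, the smallest 100000 pairings can give). Peaks are not independent replicates, and the 690 were the strongest peaks called on both replicates together, so this correlation describes the list.

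**Figure D1:**
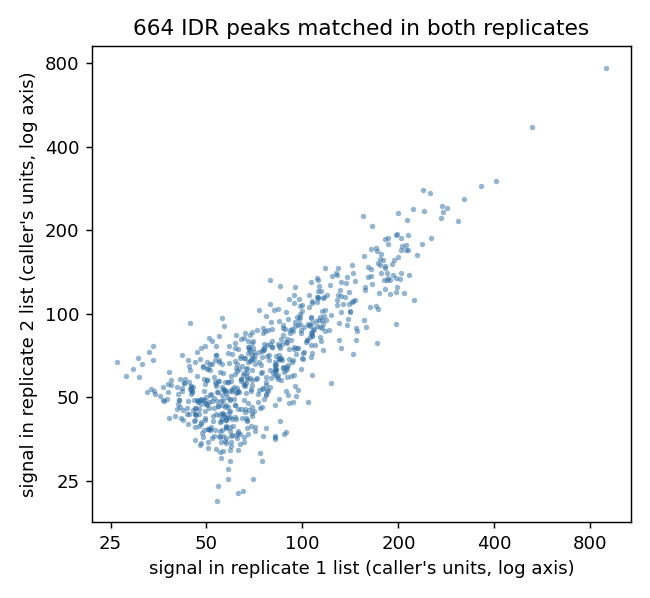
Signal of each of the 664 IDR peaks in the replicate 1 list (x axis, caller's units, log scale) and in the replicate 2 list (y axis, caller's units, log scale), 1 point per peak. Points rise together (rho = 0.75), with the widest scatter among weak peaks.

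The strongest peak (III:8043727-8044207, signal 1661) had its summit 528 bp upstream of the start of K12H4.5, in intergenic sequence. The second (III:3499814-3500252, signal 997) lay 979 bp upstream of M01F1.9 and inside the neighbouring gene M01F1.8. The third (I:5807232-5807673, signal 709) lay between lin-35, the retinoblastoma homologue, and vps-51, a vesicle tethering factor, 245 bp and 173 bp upstream of their starts. The fourth (III:7520681-7521009, signal 652) had its summit at the start of cux-7, 165 bp upstream of C07H6.2 and 619 bp upstream of lig-4, which encodes DNA ligase IV. Next came peaks upstream of Y92H12BR.2 and Y92H12BR.3 (signal 578) and of Y32B12B.4 (signal 531). A peak of signal 528 at III:5172539-5172838 lay upstream of K10D2.5, of prp-19, a splicing factor, and of emb-1, a subunit of the anaphase-promoting complex.

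The histone demethylase gene jmjd-1.2 shared a peak with F29B9.11 (IV:4660403-4660840, signal 524), and chaf-2, which encodes a chromatin assembly factor subunit, shared 1 with Y71G12B.30 (I:1822964-1823411, signal 503). The ubiquitin ligase gene eel-1 had a peak 553 bp upstream (IV:3050435-3050878, signal 494). Peaks of signal 522, 511, 489, 471, 455 and 446 lay upstream of wbp-4 with F56G4.6, Y50D4C.5, C34C12.9, sup-35 with Y48A6C.4, Y41D4A.4 with Y41D4A.6, and T07F10.3. The cyclophilin gene cyn-10 (II:6913348-6913656, signal 430), the mitochondrial ribosomal protein gene mrpl-18 with C14B9.8 (III:8144648-8144933, signal 414) and the mitofusin gene fzo-1 (II:5836375-5836736, signal 400) completed the promoter peaks. Of the 20 strongest, 19 were in promoters. The remaining peak, the eighteenth by signal, lay in an intron of hmt-1, a heavy metal tolerance transporter gene (III:11091695-11092002, signal 430).

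Summits lay mainly in promoters of protein-coding genes, defined as 1000 bp upstream to 200 bp downstream of the annotated gene start. Promoters held 435 of 690 summits, or 63.0% (Wilson 95% interval 59.4 to 66.6%), against a mean of 21.2% for shifted summits, a ratio of 2.97. Coding exons held 7 summits (1.01% against 19.9% shifted) and 3′ untranslated regions held 1 (0.145% against 2.39%). Introns outside promoters held 141 summits (20.4% against 31.3%) and intergenic sequence held 15.1% of summits (24.4% shifted). Each of these 5 classes differed from the shifted summits (two-sided permutation p = 0.002, the smallest 1000 shifts can give, and Benjamini-Hochberg adjusted p = 0.0024 over 6 classes). The 5′ untranslated regions, with 2 summits, gave a permutation p of 0.16 (0.29% against 0.837%). The median distance from a summit to the nearest gene start was 369 bp, against 1638 bp for shifted summits (permutation p = 0.002).

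**Figure D2:**
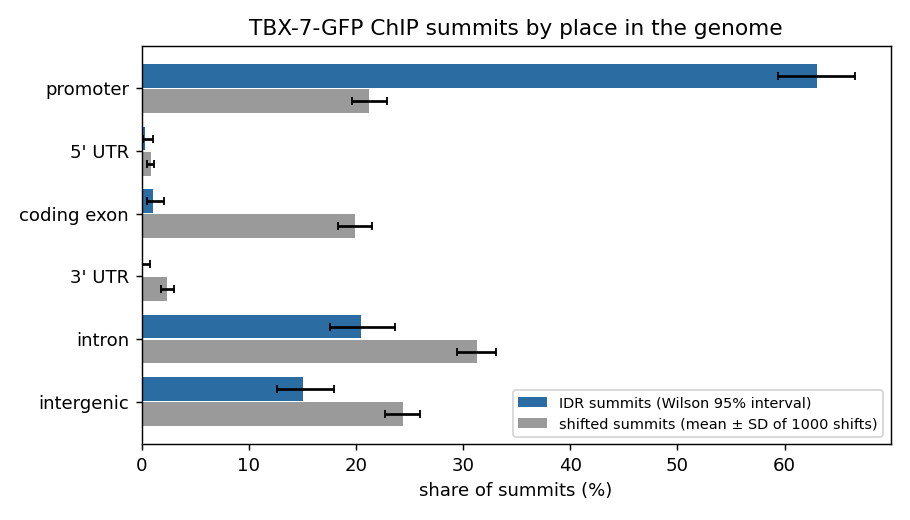
Share of the 690 summits in each class of sequence (blue, with Wilson 95% intervals) and mean share of shifted summits (grey, with the SD of 1000 shifts). The promoter bar reaches 63.0% against 21.2% for shifted summits, and the coding exon bar 1.01% against 19.9%.

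Promoter summits often lay where promoters of neighbouring genes overlap. Of the 435 promoter summits, 197 (45.3%, Wilson 95% interval 40.7 to 50%) were in the promoters of 2 or more genes, whereas 11% of promoter bases are (exact binomial p = 7.01e-73, two-sided, taking summits as independent). The reference takes summits as spread evenly over promoter bases. The test therefore does not separate a preference for shared promoters from nearness of summits to gene starts. Gene pairs such as lin-35 and vps-51 or his-67 and his-68 were counted as bound by the same peak.

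Among chromosomes, III held more summits than its length would give and V fewer. Chromosome III held 130 summits, 1.37 times its share of the genome, and V held 15.1% of summits, 0.722 times its share (exact binomial test, two-sided, Benjamini-Hochberg adjusted p = 0.000608 for each). The ratios of the others were 1.19 on I, 1.20 on II, 0.864 on IV and 0.845 on X, and none passed the test (adjusted p from 0.0596 to 0.108). Among the 345 strongest peaks the value for V was 0.792 (exact binomial adjusted p = 0.0703), and X fell to 0.476 times its share (adjusted p = 7.86e-06). Summits beside tRNA genes, described below, lay mostly on X and mostly among the weaker peaks, and the ratios were not computed without them. Without replicate 1, chromosomes I, II and X also passed the test.

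Of 19973 annotated protein-coding genes, 623 (3.12%) had at least 1 summit in the promoter. Genes of the translation machinery were bound more often. Of 78 ribosomal protein genes 15 were bound (19.2%, exact 95% interval 11.2 to 29.7%), an odds ratio of 7.55 against all other genes (Fisher's exact test, two-sided, adjusted p = 1.85e-07 over 24 lists). The bound members with the strongest peaks were rps-24 (IV:385109-385305, signal 327), rpl-3 (III:3867428-3867694, signal 282), rpl-43 (signal 226) and rpl-15 (signal 210), and the strongest summits of the 15 genes were all different. Of 68 genes for translation factors and aminoacyl-tRNA synthetases 12 were bound (17.6%, exact 95% interval 9.46 to 28.8%, odds ratio 6.77, adjusted p = 9.01e-06). They included eif-3.E (I:10642370-10642631, signal 322) and eif-3.B (signal 277), which encode subunits of an initiation factor, and the synthetase genes ears-2 (signal 252) and kars-1 (signal 217). When each summit was given only to the nearest gene start, the odds ratio of the ribosomal list fell to 3.16 (Fisher's exact adjusted p = 0.046).

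Histone genes and the list of heat shock and stress genes also passed the test, the second less firmly. Of 72 histone genes 11 were bound (15.3%, exact 95% interval 7.88 to 25.7%, odds ratio 5.68, adjusted p = 8.03e-05), but their strongest summits numbered 6 only, since histone genes lie in divergent pairs. The pair his-67 and his-68 (I:9988812-9989094, signal 326) and the pair his-31 and his-32 (IV:8334020-8334252, signal 203) had the strongest peaks. With nearest starts the odds ratio was 2.91 and the list no longer passed (Fisher's exact adjusted p = 0.0764). Histone genes occur in near-identical copies, so reads assigned there are uncertain, although 0 of the 6 summit windows consisted mostly of non-unique 36-base words. Of 40 heat shock and stress genes 5 were bound (12.5%, exact 95% interval 4.19 to 26.8%, odds ratio 4.46, adjusted p = 0.027). The strongest of these were at dnj-12, a DnaJ co-chaperone gene (signal 237), hsp-3, an endoplasmic reticulum Hsp70 (signal 158), hsp-60, the mitochondrial chaperonin (signal 158), and hsp-1, a cytosolic Hsp70 (signal 111). Under 4 alternatives the list did not pass although its odds ratio stayed near the main value: the narrower promoter window (odds ratio 4.44, Fisher's exact adjusted p = 0.0562), the 345 strongest peaks (4.26, 0.156), without replicate 1 (3.62, 0.0927), and gene starts that share a summit counted once (3.98, 0.158). Without the peaks that hold 1 of the 10 most enriched six-mers the odds ratio itself fell to 2 (Fisher's exact adjusted p = 0.962), as the strongest summit of all 5 bound genes holds such a word.

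Chemoreceptor, F-box and C-type lectin genes were bound less often than other genes. Of 1246 chemoreceptor genes of the G protein-coupled families 4 were bound (0.321%, exact 95% interval 0.0875 to 0.82%, odds ratio 0.0942, Fisher's exact adjusted p = 1.66e-11). With other promoter windows that odds ratio ran from 0.0299 to 0.153. The 4 genes were sre-23 (signal 248), sre-1 (signal 176), srh-89 (signal 137) and sri-5 (signal 92.4). Of 322 F-box genes, those with fbxa, fbxb or fbxc symbols, 1 was bound, fbxc-44 (odds ratio 0.0953, Fisher's exact adjusted p = 0.00441). The bound gene fbxl-2 lay outside these symbols and was counted among the other genes. Of 240 C-type lectin genes 1 was bound, clec-126 (odds ratio 0.129, Fisher's exact adjusted p = 0.027). The odds ratios of both lists stayed low where the call was lost. Without the peaks that hold 1 of the 10 most enriched six-mers the F-box list had 0.239 (Fisher's exact adjusted p = 0.684), with fewer peaks left to test, and the summit at fbxc-44 holds none of these words. The lectin list had odds ratios from 0 to 0.217 under the 5 alternatives in which it did not pass (Fisher's exact adjusted p from 0.0846 to 0.426).

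Genes that mark tissues or specify cell fates gave few bound members. None of the 21 T-box genes examined had a summit in the promoter, and the same held for 28 pharyngeal, 35 intestinal, 46 epidermal, 37 pan-neuronal and 51 ciliary genes, 59 developmental transcription factors, 63 ceh homeobox genes and 25 hlh genes. Each list alone is too short to show a depletion: a count of 0 allows a share of up to 14.3% in the T-box list and 4.76% in the ceh list, above the 3.12% of all genes, and none of these lists passed the test (adjusted p from 0.538 to 1). The body wall muscle list had 1 of 41 bound, cpn-3, which encodes a calponin-like protein (signal 111). The germ line list had 1 of 48, mex-1, which encodes an RNA-binding protein of the early embryo (II:11967592-11967889, signal 389). The Wnt list had 1 of 33, mom-1, which acts in Wnt secretion (signal 103), and the Notch list had 1 of 33, the metalloprotease gene adm-4 (signal 158); all 4 lists had an adjusted p of 1.

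The other families did not pass the test. Of 269 nuclear hormone receptor genes 2 were bound, nhr-142 (signal 154) and nhr-255 (signal 99.7), with an odds ratio of 0.23 and an adjusted p of 0.0589. That list passed in the same direction with the wider promoter window (Fisher's exact adjusted p = 0.0105), with upstream distance in a logistic model (0.0201), without replicate 2 (0.0131) and without peaks near small RNA genes (0.0173). Of 33 proteasome genes 3 were bound, pas-1, pas-3 and pbs-3 (odds ratio 3.12, Fisher's exact adjusted p = 0.22), the strongest peak being at pas-1 (signal 168). Of 41 genes taken by symbol for the respiratory chain and ATP synthase 3 were bound, atp-5, cox-6A and cox-5B (signal 207, 102 and 96.2, odds ratio 2.46, Fisher's exact adjusted p = 0.325). The symbols did not cover the whole class. The genes ndua-2 and nduc-2 were bound, lay outside the list and were counted among the other genes, so these values hold for the listed symbols only. That list passed with the wider promoter window (odds ratio 4.31, Fisher's exact adjusted p = 0.0121). Of 156 collagen genes 4 were bound, col-71, col-2, col-142 and col-185, with the strongest peak at col-71 (signal 236; odds ratio 0.816, Fisher's exact adjusted p = 1).

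**Figure D3:**
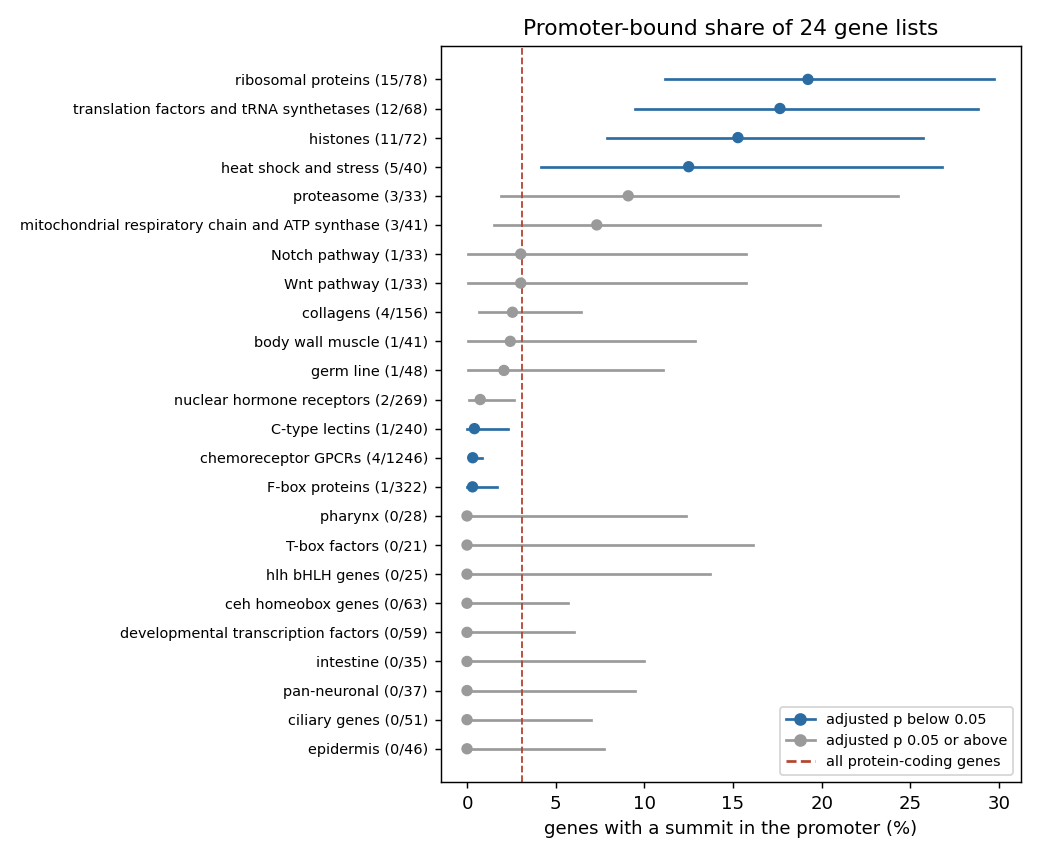
Share of genes with a summit in the promoter for each of the 24 gene lists (points, with exact 95% intervals; bound and total genes in parentheses), coloured blue where the adjusted p of Fisher's exact test was below 0.05. The dashed line marks the 3.12% of all protein-coding genes, and ribosomal protein genes lie furthest above it at 19.2%.

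Summits were also frequent at genes for small non-coding RNAs. Within 200 bp of a tRNA gene lay 78 summits, against a mean of 1.83 for shifted summits, a ratio of 42.7. Within 200 bp of a small nucleolar, small nuclear or ribosomal RNA gene lay 52 summits, against 1.88, a ratio of 27.6 (two-sided permutation p = 0.002 for both, the smallest 1000 shifts can give). The counts changed little with the distance allowed but the ratios did, from 67.3 within 100 bp to 20.9 within 500 bp for tRNA genes and from 40.5 to 15.4 for the others. In all, 130 of 690 summits (18.8%) lay beside such a gene, among them 31.9% of the intronic and 43.3% of the intergenic summits but 8.74% of those in promoters. The strongest peak beside a small nucleolar RNA gene was at V:12303494-12303769 (signal 363), next to C51F7.3 and C51F7.4 in an intron of frm-7. The strongest beside tRNA genes was at X:9743404-9743847 (signal 220), in an intron of him-4, and the strongest beside a small nuclear RNA gene was at I:4172066-4172509 (signal 209), beside the spliced leader gene sls-2.4. These 3 were named after their values were seen. Genes read by RNA polymerase III are often found in ChIP peak lists of unrelated factors, and no peak list of another factor was analysed here. None of the 20 strongest peaks lay beside a small RNA gene.

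**Figure D4:**
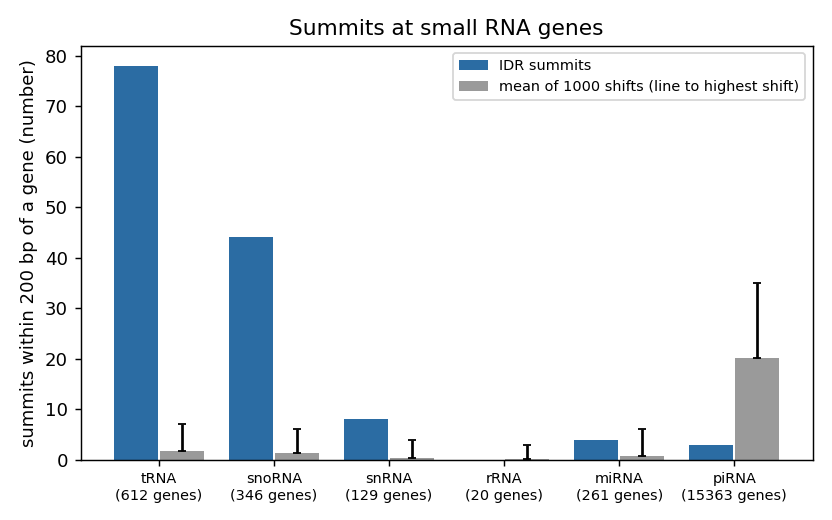
Number of summits within 200 bp of a gene of each small RNA class (blue) and mean number over 1000 shifts (grey, with a line up to the highest shift). At tRNA genes 78 summits stand against a mean of 1.83, while piRNA genes show 3 against 20.1.

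The word AGGTGTGA, bound by T-box proteins, was sought in windows reaching 50 bp to either side of each summit. It occurred in 0 of 690 windows, which allows a share of up to 0.435%, and in 0% of flanking windows 500 bp away. The exact McNemar test (two-sided, p = 1) had no windows that differed, so its outcome was fixed by these counts. The shorter GGTGTGA also occurred in 0 windows and in 0.29% of the flanking windows tested (exact McNemar p = 0.5). The five-base core GGTGT occurred in more windows (17.2%, Wilson 95% interval 14.6 to 20.2%) against 7.39% of the flanking windows tested (exact McNemar p = 1.28e-08). Against the opposite flank of each summit, a comparison added after the data were seen, the share was 11.2% (exact McNemar p = 0.00149). Summit windows had a higher mean GC content than flanking windows (48.1% against 36.9%), which neither comparison of GGTGT takes into account. The excess of GGTGT therefore does not by itself show binding by a T-box protein. Of the 2150 copies of AGGTGTGA in the genome 3 lay inside an IDR peak, where 5.65 would be placed by coverage alone (exact binomial p = 0.394, two-sided). The 345 strongest and 345 weakest peaks both held 0 windows with AGGTGTGA (Fisher's exact p = 1, fixed by the counts of 0). The test therefore says nothing on peak strength for that word. GGTGT occurred in 18.6% of the strongest and 15.9% of the weakest (Fisher's exact p = 0.42).

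Words built on GGCC were far more frequent at summits than beside them. The 5 six-mers with the smallest p among the enriched were CGGCCA (18.7% of summit windows against 1.74% of flanking windows), GGCCAC (19.3% against 2.17%), GGCCTA (17.5% against 1.74%), AGGCCA (113 windows against 13) and GGCCGA (15.1% against 1.59%). Their adjusted p ran from 3.21e-24 to 1.44e-19 (exact McNemar test, two-sided, adjusted over all six-mers, both strands). The 5 leading depleted six-mers were CTGAAA (6.38% against 25.4%), AAATTA (8.12% against 24.5%), TGAAAA (15.2% against 33.8%), AAAAAA (20.3% against 39.7%) and AAAATT (21.2% against 39.9%), with adjusted p from 3.98e-19 to 3.09e-12. In all, 362 six-mers were enriched and 273 depleted. Summit windows had a mean GC content of 48.1% ± 8.24 (SD, n = 690 windows) and flanking windows 36.9% ± 8.59, and 570 summits exceeded their flank while 106 fell under it (exact sign test p = 1.08e-77). Against dinucleotide-shuffled copies of the same windows, a background added after the data were seen, 5.58% of six-mers were enriched, in place of 17.4% against flanks.

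**Figure D5:**
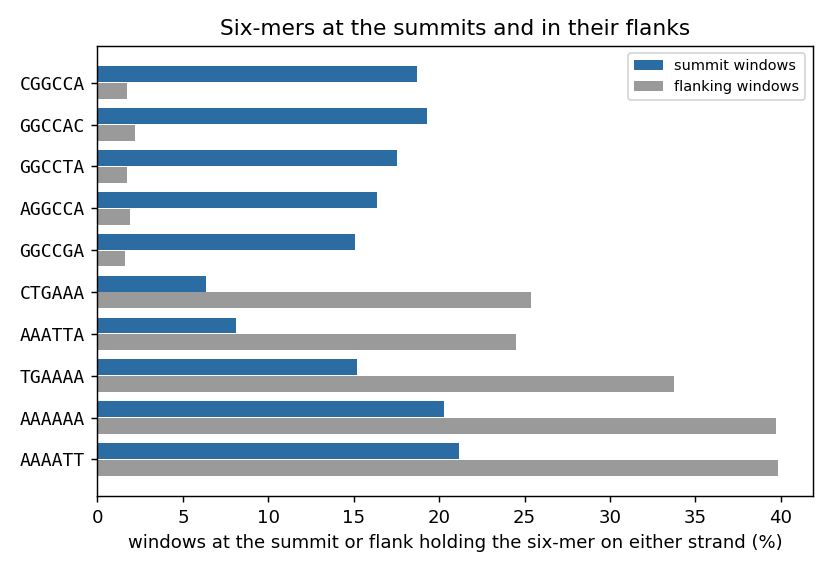
Share of summit windows (blue) and flanking windows (grey) that hold each of the 10 named six-mers on either strand. CGGCCA is in 18.7% of summit windows against 1.74% of flanking windows, and CTGAAA in 6.38% against 25.4%.

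At the fourth strongest peak, the 41 bases centred on the summit (III:7520824-7520864, in the overlapping promoters of cux-7, C07H6.2 and lig-4) read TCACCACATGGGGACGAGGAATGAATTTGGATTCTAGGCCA and end in 1 copy of AGGCCA. At the strongest peak they read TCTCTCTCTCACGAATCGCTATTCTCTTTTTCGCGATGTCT (III:8043939-8043979, upstream of K12H4.5), and its window held none of the 10 most enriched six-mers. The fourth peak is the strongest whose window holds CTAGGCCA, the most frequent 8-base word, and was chosen after the sequences were seen.

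The tbx-7 gene itself (III:6024958-6028532, minus strand) had no IDR summit within 20 kb, where shifted summits gave a mean of 0.407 (permutation p = 1). Its nearest summit was 156555 bp from the gene start. The count was also taken for unc-119 (III:10902641-10908935), which is often the rescue marker of such transgenic lines, although the labels do not say so for this strain. The unc-119 gene had 0 summits within 20 kb against a shifted mean of 0.423 (permutation p = 1), and its nearest summit was 44795 bp from the gene start. Both tests had too few summits to show a depletion.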

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

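The following values come from peaks outside the final list, and this comparison was chosen after the data were seen. Of the 690 series-wide peaks ranked 691 to 1380, just under the IDR threshold, 586 (84.9%, Wilson 95% interval 82.1 to 87.4%) had a summit within 100 bp in both replicate lists. Shifted positions gave a mean of 0.612% and at most 1.59% over 100 shifts. Of these peaks 309 (44.8%) had summits in promoters, compared with 63.0% in the IDR list. The series-wide peaks were called on the reads of the same 2 replicates against the same control and were matched to permissive lists of 16060 and 9840 peaks. A high share is therefore partly built in, and the shifts show only the rate of chance overlap.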

How the results depend on the processing

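Over 346 combinations of a result with an alternative setting, 289 kept their direction and their side of the threshold or stayed within 1.5 times the count. Promoter share (53.0 to 72.8% with other windows, peaks or replicates), summits at tRNA genes, replicate overlap (55.6 to 78.3%) and rank correlation (rho from 0.62 to 0.75) did so in every alternative run. No paired analysis was possible because the design holds 1 group. By construction, taking the stronger peaks left 345 peaks. Chromosomes past the threshold rose from 2 to 5 with the ce10 list, and ranged from 2 to 5 without 1 replicate. The T-box result passed only with the core GGTGT (17.2% of windows), against flanks of lower GC content. Against dinucleotide-shuffled windows 5.58% of six-mers were enriched, in place of 17.4%. Without peaks holding 1 of the 10 leading six-mers, 4 lists passed in place of 7. Lists called in the main test kept their direction throughout. Among lists that were not called, with 4 or fewer bound genes, the odds ratio crossed 1 in some settings without passing the threshold. Of the values below, 0.98 (Notch), 0 (Wnt) and 2.48 (respiratory chain), each without 1 replicate, stayed on the side of the main test. For the Notch list it was 1.24 (narrow window), 1.63 (stronger peaks), 1.12 (without the strongest 10%), 1.01 and 0.98 (without replicates 1 and 2), 1.03 (upstream distance), 1.44 (shared starts once) and 1.05 (without small RNA peaks). For the Wnt list it was 1.61 (wide window), 3.2 (nearest start), 1.12 (without the strongest 10%), 0 and 3.15 (without replicates 1 and 2), 1.1 (upstream distance), 2.43 (without six-mer peaks) and 1.44 (shared starts once). For the muscle list it was 1.28 (wide window), 1.63 (nearest start) and 1.16 (shared starts once). For the germ line list it was 1.11 (stronger peaks), 1.41 and 1.37 (without replicates 1 and 2) and 1.65 (without six-mer peaks). Collagens gave 1.28 and the proteasome 0.995 with nearest starts, and the respiratory chain 0.811 and 2.48 without replicates 1 and 2, and 0 without six-mer peaks. The unc-119 gene had 2 summits within 50000 bp, above the shifted mean of 0.939. The cause was not tested for these. The number of libraries limits all statements on replicates, and the small lists limit what a count of 0 can show.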

Other observations

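The comparisons in this part were chosen after the data were seen, and of the tests on the 3 patterns weighed below, the second of the 2 on tRNA copies was chosen after the first result was seen and those on shuffled windows and left-out peaks were added after the data were seen, while the leading words and the GC content were known before the tests on them were set. Separated by class, 84 of 612 tRNA genes (13.7%), 45 of 346 small nucleolar RNA genes (13.0%) and 9 of 129 small nuclear RNA genes (6.98%) had a summit within 200 bp, while 0 of 20 ribosomal RNA genes did. The 44 summits at small nucleolar RNA genes belonged mostly to the stronger peaks (30 of 44 among the 345 strongest, exact binomial p = 0.0226), whereas the 78 at tRNA genes belonged mostly to the weaker (16 of 78, p = 1.51e-07). Summits were few at piRNA genes, with 3 against a shifted mean of 20.1 (permutation adjusted p = 0.003). At microRNA genes there were 4 against 0.797 (permutation adjusted p = 0.0312), while the highest shift gave 6. The strongest lay beside mir-51 (IV:11026089-11026332, signal 285). The mir-52 gene had neighbouring summits (signal 207 and 127), so the 4 are not all separate sites. Some genes named as bound had their summit beside a small RNA gene: sre-23 beside the small nucleolar RNA gene ZK265.10, cox-6A beside the small nuclear RNA gene F54D8.7, and clec-126, mom-1, nhr-255 and col-185 beside tRNA genes. Without such peaks the C-type lectin and Wnt lists therefore had 0 bound genes.

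All 7 tissue lists joined had 2 of 286 genes bound (0.699%, exact 95% interval 0.0848 to 2.5%) against 3.15% of other genes, and all 5 transcription factor lists joined had 2 of 424 (0.472%, exact 95% interval 0.0572 to 1.69%) against 3.18% (Fisher's exact p = 0.00978 and p = 0.000312, two-sided). The 4 bound genes were cpn-3, mex-1, nhr-142 and nhr-255. The idea of joining lists followed from their low single counts, so these p-values describe the lists and are not an independent test.

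Enriched words differed between strong and weak peaks. GGCCTA occurred in 24.6% of the 345 strongest and 10.4% of the 345 weakest peaks (Fisher's exact adjusted p = 4.14e-06 over 7 words), while AGAGAG occurred in 5.51% and 19.1% (adjusted p = 3.48e-07). The most frequent 8-base word, CTAGGCCA, was in 81 summit windows and 2 flanking windows. A 14-base word, CGAGAGGAGTACAC, was in 21 summit windows and 0 flanking windows, and 26 of its 122 genome copies (21.3%) lay in IDR peaks, which cover 0.263% of the genome. Another, ACGAAAAGGGGAGC, was in 13 summit windows and 1 flanking window, and had 56 of its 177 copies (31.6%) in IDR peaks. Copies were counted over whole peaks, and 1 peak can hold several, so these are not numbers of separate sites. GGTTCGA, the core of the internal promoter of tRNA genes, was in 39 summit windows, 26 of them at tRNA genes, and in 2 flanking windows (exact McNemar p = 7.84e-10). Peaks with 1 of the 10 leading six-mers lay beside small RNA genes as often as others (18.8% of 352 against 18.9% of 338, Fisher's exact p = 1), and 274 of 690 peaks (39.7%) had neither.

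The shared words at summits were tested against 3 explanations. Base composition as the whole cause is argued against, since 9 of the 10 leading six-mers stayed enriched over shuffled windows of the same dinucleotides. These six-mers were picked for their frequency in the same windows, which favours this outcome, and the shuffles keep dinucleotide composition only. Reads placed among identical copies of at least 36 bases are argued against too. Of the windows with these words 1.99% consisted mostly of non-unique 36-base words (exact 95% interval 0.803 to 4.05%), against 10.1% of other summit windows. This measure does not cover repeat copies that differ in some bases, and the read length was not given in the sources used here. Whether the words belong to diverged repeats was not tested. Location of the copy may matter: copies of CTAGGCCA in promoters lay in IDR peaks in 10.2% of cases and others in 0.208% (Fisher's exact p = 1.52e-63), although IDR peaks as a whole favour promoters. Whether TBX-7 or another protein recognises the words, and whether the same regions appear with other immunoprecipitated factors, stays open, and no biological explanation was tested.

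The binding at ribosomal protein, translation factor and histone genes was weighed in the same way. All 3 lists passed with distance to the next upstream gene in a logistic model, which argues against free upstream space as the whole cause. The 3 lists also passed without the peaks holding 1 of the 10 leading six-mers, and 3 passed without peaks within 200 bp of a small RNA gene. This argues against these 10 six-mers or a small RNA gene beside the promoter as the whole cause. Peaks that hold only other enriched words were kept, so shared sequence words in general were not tested. Of the strongest summits, 6 of 15 ribosomal, 7 of 12 translation factor and 2 of 6 histone ones held 1 of these six-mers. All these tests take genes that share a summit as independent, and the histone list did not pass with nearest starts. High transcription of these genes, which could raise recovery of open chromatin in any ChIP experiment, was not tested, because no expression data, control reads or other peak lists were analysed here.

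Reads of 1 tRNA copy placed at another copy could give summits at tRNA genes, and the share of these 78 windows that consist mostly of non-unique 36-base words (19 windows, 24.4%, exact 95% interval 15.4 to 35.4%) lay between the bounds of 10% and 50% set beforehand, so that copies as a contribution stay open. A second measure was therefore chosen after the first was seen: 23 windows held no such word at all, more than the 7 tRNA summits of the highest shift, which argues only against copies as the whole cause, since the read length was not given in the sources used here. Recovery of polymerase III genes irrespective of the antibody stays open, and no biological explanation was tested.

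No summit lay within 20 kb of tbx-7 in any of the 3 lists before the IDR test, where uniform placement would give 3.81 in the series-wide list, 6.98 in replicate 1 and 4.28 in replicate 2. The gap around the gene measured 89.7 kb in the series-wide list, 71.7 kb in replicate 1 and 84.5 kb in replicate 2. Gaps of at least that length numbered 31 of 8753, 9 of 16054 and 17 of 9834. Of 10000 random windows as long as the gene with 20 kb to either side, which is shorter than these gaps, 6.09%, 1.22% and 3.92% held no summit in these lists. The 3 lists share reads and a control, so they are not independent of each other. The cause was not tested, and the control, filtering of peaks by the authors and the set of peaks used here all stay open.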
